A study of Sus scrofa domesticus with 12 samples.

How the data were processed

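Single-nucleus RNA sequencing was done on the right ventricular free wall of 12 male pigs, 4 in each of 3 groups: control, PAB with vehicle and PAB with SC144. Nuclei were isolated from frozen tissue, flow sorted and captured in 10x Genomics droplets, 1 library per pig. The deposited matrices hold raw UMI counts per gene and barcode and no normalized values. The submitters' processing notes name Cell Ranger 7.2.0 and the pig genome build Sscrofa10.2. The same 21607 gene IDs are listed for every pig, of which 13516 carry a symbol in the deposited files, 1750 were given one by a table of gene names and 6341 have none. Empty droplets are not in the deposited matrices, so free RNA was not analysed here by an ambient profile. Raw reads, heart function and tissue measurements were not analysed here.

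Barcodes per pig ranged from 6858 to 24673, the sum of UMIs per pig from 18496862 to 78385584 and the median UMIs per barcode from 1993 to 3115. Mean summed UMIs were 37304292 in control, 70540554 in PAB-vehicle and 47600608 in PAB-SC144 pigs. Nuclei with at least 500 UMIs, at least 300 genes and at most 5% mitochondrial UMIs passed, 193991 of 194106 barcodes. Doublets were scored in each pig with Scrublet as in scanpy 1.11.5, and in each pig the share of top scores was 0.8% per 1000 barcodes, 27332 in all, removed after clustering, which left 166659 nuclei. This share grows with the number of barcodes, and so more nuclei were removed from the pigs with more barcodes.

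Clustering used 2000 variable genes with the pig as batch key, 30 principal components, 15 neighbours and Leiden resolution 1, without integration across pigs, and gave 25 clusters. The Leiden step was that of igraph, called through scanpy (Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, matplotlib 3.10.9). They were named from 15 marker lists into 11 classes, written as "-like", and 4 clusters stayed unnamed. The marker lists were fixed before the data were examined. The smallest fold of a marker (2), the rule that a cluster with over 50% doublets stays unnamed and the rule for cell cycle clusters were set after the clusters were seen. A pig and class entered with at least 20 nuclei, and genes were tested in cardiomyocyte-, fibroblast-, vascular endothelial-, pericyte- and macrophage-like nuclei.

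Counts were summed per pig and class and fitted for all 12 pigs at once with edgeR 4.0.16 quasi-likelihood (R 4.3.3, TMM factors, the package's low-count filter), with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. The comparisons were PAB-vehicle against control and PAB-SC144 against PAB-vehicle in 5 classes, and PAB-SC144 against control in cardiomyocyte-like nuclei. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F. The 36 gene lists and the 15 marker lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, and again with an estimated correlation and with fry. fry tests whether the genes of a list move, on balance, one way and does not compare them with other genes. Of 110 list calls by camera, 2 held with an estimated correlation (interferon response genes in cardiomyocyte-like nuclei of SC144 against control pigs and in pericyte-like nuclei of SC144 against vehicle pigs). By fry 11 held. None of these came from banding outside cardiomyocyte-like nuclei, or from SC144 against vehicle pigs outside pericyte-like nuclei. Median, mean and direction of the test had the same sign in each called list. Groups of pigs for shares and list means were compared by exact permutation of 70 assignments.

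Comparisons, tests, gene lists, all but 2 of the other settings and the rule for named genes were chosen before the data were examined. The rule names IL6ST in every class, then up to 4 members with the smallest adjusted p of each list that camera called or that held at least 2 changed genes, and then the changed genes with a symbol, a log2 change of at least 1 and no overlap between the groups. Of these the 5 higher and 5 lower with the smallest adjusted p were taken, 8 and 8 in cardiomyocytes. Where this gave over 30 genes, 2 members per list were taken, and outside cardiomyocytes genes over 3 times higher in cardiomyocytes were passed over. Other members of lists named with their values were chosen after those values were seen, as the members with the smallest p or as known members of the list. Leaving out nuclei with at least 2% of UMIs from 23 cardiomyocyte markers, and keeping clusters rich in doublets, were added after the data were seen.

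The alternatives were DESeq2 1.42.0, RLE factors, no low-count filter, 1000 UMIs per nucleus, doublets kept, Leiden resolution 0.5, a fit of the 2 compared groups alone, the replicate number as a block, libraries thinned to the smallest, genes higher in cardiomyocytes left out, shares among nuclei that are not cardiomyocytes, and each pig left out. On simulated counts with 100 genes changed by a log2 of 1 or 2, edgeR recovered, after banding, 29 and 86 in cardiomyocytes, 36 and 87 in fibroblasts, 14 and 77 in vascular endothelial nuclei, 35 and 85 in pericytes and 35 and 83 in macrophages. Between SC144 and vehicle pigs it recovered, in the same order, 39 and 89, 40 and 91, 18 and 85, 34 and 86 and 43 and 93, and between SC144 and control pigs 44 and 91 in cardiomyocytes. Camera called a simulated changed list in each of the 5 classes and 0 of 40 unchanged lists in each. The simulated genes varied independently of each other. These counts therefore do not show how often camera calls unchanged lists of correlated genes. Pigs of a group were checked for duplicated libraries, and the lowest chi-square per degree of freedom between any pair was 28.9.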

Results

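Nuclei from the right ventricular free wall of 12 male pigs were compared between 4 control pigs, 4 pigs with pulmonary artery banding (PAB) given vehicle and 4 pigs with PAB given SC144. SC144 is an inhibitor of GP130, the shared signalling subunit of the IL-6 family of receptors, which IL6ST encodes. Each change below is a log2 fold change ± its standard error between groups of 4 pigs, and each share is a mean ± SD over pigs.

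Cardiomyocyte-like nuclei made up 69.9 ± 9.03% of the named nuclei in control pigs and 49.1 ± 3.63% in PAB-vehicle pigs, with 4 of 4 vehicle pigs below every control pig. Macrophage-like nuclei were 4.75 ± 1.36% and 13.6 ± 2.28%, and T or NK cell-like nuclei 3.08 ± 0.544% and 8.81 ± 3.35%. Pericyte-like nuclei were 3.72 ± 0.319% and 7.15 ± 1.1%, and vascular endothelial-like nuclei 2.24 ± 0.337% and 4.07 ± 1.04%, each of these 4 classes with 4 of 4 vehicle pigs above every control pig. For each of the 5 classes the exact permutation p was 0.0286, the smallest that 70 assignments can give, and the adjusted p over 22 tests was 0.126, so no share passed 0.05 after adjustment. The shares of a pig add up to the whole. A lower cardiomyocyte-like share by itself raises the others, so the 4 higher classes are not separate from it. Fibroblast-like nuclei were 12.9 ± 6.98% and 13.2 ± 2.38% (exact p = 0.943, adjusted p = 0.988), a difference of 0.338 percentage points that was -0.672, -1.85 and -0.662 without control pig 1 or 4 or vehicle pig 4. Among nuclei that are not cardiomyocyte-like it was -14.4 points. B cell-like, neural or Schwann-like, endocardial-like, lymphatic endothelial-like and smooth muscle-like shares had exact p from 0.114 to 0.943. The nuclei were flow sorted before capture, and vehicle pigs gave 69703 kept nuclei against 42841 in controls, with 16.8% and 9.55% of barcodes left out as doublets. In control, vehicle and SC144 pigs, unnamed clusters rich in doublets held 2.39, 0.921 and 1.26% (cluster 1, fibroblast markers), 1.31, 0.385 and 1.22% (cluster 2, macrophage markers) and 1.20, 0.148 and 1.13% (cluster 14, T or NK cell markers) of kept nuclei. Without SC144 pig 4 the SC144 means were 0.783, 0.545 and 0.707%, cluster 1 held 0.575% in vehicle pigs without vehicle pig 2, and cluster 2 0.868% in controls without control pig 2. Unnamed cluster 10, with cell cycle genes, held 1.31, 0.507 and 2.27%.

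**Figure D1:**
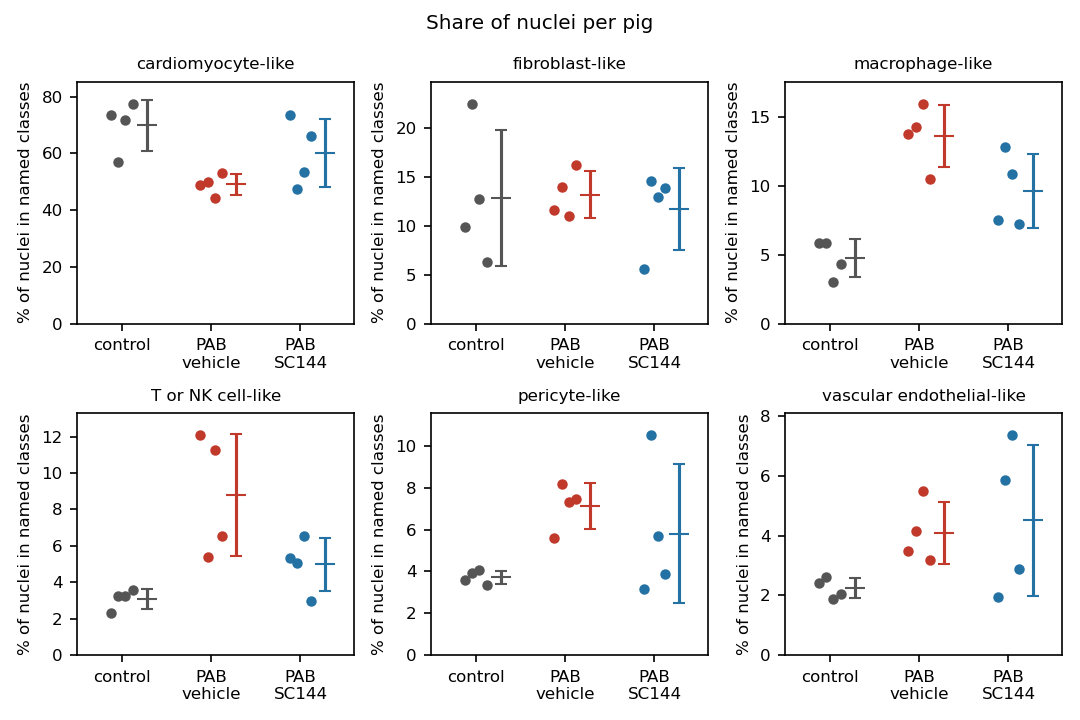
Percent of the nuclei in named classes that belong to each of 6 classes, one point per pig, with lines for the mean ± SD of 4 pigs. Cardiomyocyte-like nuclei average 69.9% in control, 49.1% in PAB-vehicle and 60.2% in PAB-SC144 pigs.

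In cardiomyocyte-like nuclei, 862 of 14988 genes changed between PAB-vehicle and control pigs, 544 higher and 318 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Among the genes that rose were TLL2, a tolloid protease that trims matrix precursors (4.49 ± 0.49, adjusted p = 0.00343), and NID2, which links basement membrane proteins (1.68 ± 0.19, adjusted p = 0.00343). ECE1, which makes mature endothelin-1, rose by 1.94 ± 0.28, the transcription coregulator TRERF1 by 1.89 ± 0.24, the kinesin motor KIF3C by 1.81 ± 0.26 and FCHSD1, a membrane-bending adaptor of actin, by 1.51 ± 0.21. FAM71B (3.35 ± 0.45) and CALR3, a calreticulin-like chaperone (1.49 ± 0.22), also rose. The mean CPM of FAM71B was low, at 0.594 in controls and 6.19 in vehicle pigs. Genes that fell included the adhesion receptor TENM2 (-1.55 ± 0.24, adjusted p = 0.00932), the ligand EDA (-1.61 ± 0.27), the Golgi protein GOLM1 (-1.26 ± 0.22), the RNA-binding gene RAVER2 (-1.89 ± 0.31) and PDSS1, which starts coenzyme Q synthesis (-1.18 ± 0.21). RD3L (-4.13 ± 0.38, adjusted p = 5.47e-04) and NOXA1, an activator of NADPH oxidase (-2.83 ± 0.34), fell from low levels, with mean CPM of 1.22 and 1.27 in controls.

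The nuclear-encoded genes of oxidative phosphorylation fell in cardiomyocyte-like nuclei of PAB-vehicle pigs: 18 of 66 tested members fell, 0 rose and the rest did not pass, and 65 had a fold change below 0 (median -0.44). Adjusted over the list alone, 45 members fell. Examples are the complex I subunit NDUFB6 (-0.67 ± 0.12, adjusted p = 0.0135) and UQCRFS1, the iron-sulfur protein of complex III (-1.06 ± 0.19, adjusted p = 0.0135). The list was called by camera (adjusted p = 9.04e-18) and by fry (adjusted p = 0.00672), and gave adjusted p = 0.491 with an estimated correlation. In the list of the tricarboxylic acid cycle, 3 of 19 members fell (13 adjusted over the list alone), among them IDH3A of isocitrate dehydrogenase (-0.72 ± 0.15) and DLST of the oxoglutarate dehydrogenase complex (-0.58 ± 0.13). Its median was -0.47 (camera adjusted p = 4.71e-06, adjusted p = 0.501 with an estimated correlation). The glycolysis enzymes PGAM1 (-0.84 ± 0.17) and TPI1 (-0.88 ± 0.18) fell, 2 of 20 list members, with a camera adjusted p of 0.139. In branched-chain amino acid catabolism ACADSB fell (-0.5 ± 0.11) and HIBCH rose (0.65 ± 0.17), 2 of 18 members (camera adjusted p = 0.173). Fatty acid oxidation had a median of -0.20 over 27 members (camera adjusted p = 0.173) and the 13 transcripts of the mitochondrial genome a median of 0.15 (camera adjusted p = 0.397). Ribosomal protein genes, a list for RNA quality, had a median of -0.15 (camera adjusted p = 0.0375, adjusted p = 0.830 with an estimated correlation). The ribosomal call ended without control pig 1 or 2 or vehicle pig 1 or 2 (adjusted p = 0.485, 0.0982, 0.129 and 0.455).

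Interferon response genes rose in cardiomyocyte-like nuclei after banding, 6 of 27 members by edgeR and 12 adjusted over the list alone, with 0 lower (median 0.60). IFI44, an interferon-induced cytoplasmic protein, rose by 3.02 ± 0.47, adjusted p = 0.0111, and PARP9, a partner of the ubiquitin ligase DTX3L, by 1.04 ± 0.19, adjusted p = 0.0158. The camera adjusted p was 2.18e-05 (adjusted p = 0.114 with an estimated correlation). In TGF-beta signalling 2 of 17 members rose, LTBP1 (2.07 ± 0.40) and LTBP2 (1.48 ± 0.31), both binders of latent TGF-beta (median 0.47, camera adjusted p = 0.00217, adjusted p = 0.501 with an estimated correlation). Endothelial activation genes rose in 3 of 12 members, among them the VEGF receptor FLT1 (1.12 ± 0.20) and the adhesion molecule SELP (1.28 ± 0.31), with a camera adjusted p of 0.0165 (adjusted p = 0.501 with an estimated correlation). PPARG, a nuclear receptor of lipid storage (1.26 ± 0.30), and the carbonic anhydrase CA4 (2.29 ± 0.59) rose, 2 of 6 endothelial fatty acid genes (camera adjusted p = 0.1). Levels of CA4 were low, with mean CPM of 0.374 in controls and 1.96 in vehicle pigs. FLT1 and CA4 are also the 2 of 18 vascular endothelial markers that rose, a list with a median of 0.22 (camera adjusted p = 0.268). Markers of other cell types moved with these groups: macrophage markers had a median of 0.19 (camera adjusted p = 0.0264, adjusted p = 0.636 with an estimated correlation), with C1QA of complement rising by 1.30 ± 0.34. C1QA too was low, with mean CPM of 0.853 in controls and 2.08 in vehicle pigs. Pericyte markers had a median of 0.27 (camera adjusted p = 0.0372, adjusted p = 0.541 with an estimated correlation). Resident macrophage genes had a median of 0.43 (camera adjusted p = 0.0264, adjusted p = 0.501 with an estimated correlation). The call of macrophage markers ended without control pig 2 or vehicle pig 1 or 3 (adjusted p = 0.0982, 0.0709 and 0.0599). That of pericyte markers ended without control pig 2 or vehicle pig 2 or 3 (adjusted p = 0.117, 0.0754 and 0.0599). Resident macrophage genes lost their call without control pig 2 or 4 or vehicle pig 2 (adjusted p = 0.0639, 0.0574 and 0.0754).

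Other fixed lists held single changed genes without a call of the list by camera. The matrix genes FBN2, a fibrillin of elastic microfibrils (3.32 ± 0.74), and THBS2, a matricellular glycoprotein (1.40 ± 0.35), rose, 2 of 34 members (camera adjusted p = 0.0609). ABCC9, the sulfonylurea receptor of cardiac potassium channels, rose under both of its gene IDs (0.84 ± 0.15 and 0.65 ± 0.16), the 2 of 15 mural contractile members that did (camera adjusted p = 0.150). BIN1, which shapes T-tubules (1.57 ± 0.34), and the calcium-handling gene ASPH (0.78 ± 0.20) rose, 2 of 17 members (camera adjusted p = 0.715). Of 19 microtubule genes, SVBP, a partner of tubulin detyrosinases, rose by 2.20 ± 0.60 and the stabilising protein MAP4 fell (-0.90 ± 0.23) (camera adjusted p = 0.360). BIN1 and SVBP were at low levels, with mean CPM of 0.663 and 0.164 in controls and 1.92 and 0.735 in vehicle pigs. Of 16 hypoxia genes, MXI1, an antagonist of MYC (0.99 ± 0.24), and PFKFB4, a regulator of glycolysis (0.59 ± 0.16), rose (camera adjusted p = 0.618). The stress transcription factors DDIT3 (-1.25 ± 0.29) and ATF4 (-0.84 ± 0.20) fell, 2 of 13 endoplasmic reticulum stress genes (camera adjusted p = 0.237). Of 18 genes of GP130 cytokines, receptors and signal carriers, those that rose included the kinase JAK1 (0.79 ± 0.22; list camera adjusted p = 0.304). IL6ST itself was at 0.38 ± 0.18, adjusted p = 0.197, and 24 STAT3-responsive genes had a median of 0.34 (camera adjusted p = 0.379).

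On average, different clusters held most cardiomyocyte-like nuclei of control and of vehicle pigs. Cluster 7 held 61.2% of them in control pigs and 1.88% in vehicle pigs (1.11% without vehicle pig 1), and cluster 8 0.966% and 59.0%. In control pig 1 cluster 7 held 15.2% and cluster 4 48.9%, and without that pig cluster 7 held 76.6% in controls. DESeq2 called 1785 genes in the same comparison. The edgeR count was 324, 305 and 115 without control pig 2, 3 or 4, 156, 302 and 316 without vehicle pig 2, 3 or 4, and 385 in libraries thinned to one depth. Of 47 genes past the threshold looked up one by one, 19 passed in every fit with a pig left out.

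**Figure D2:**
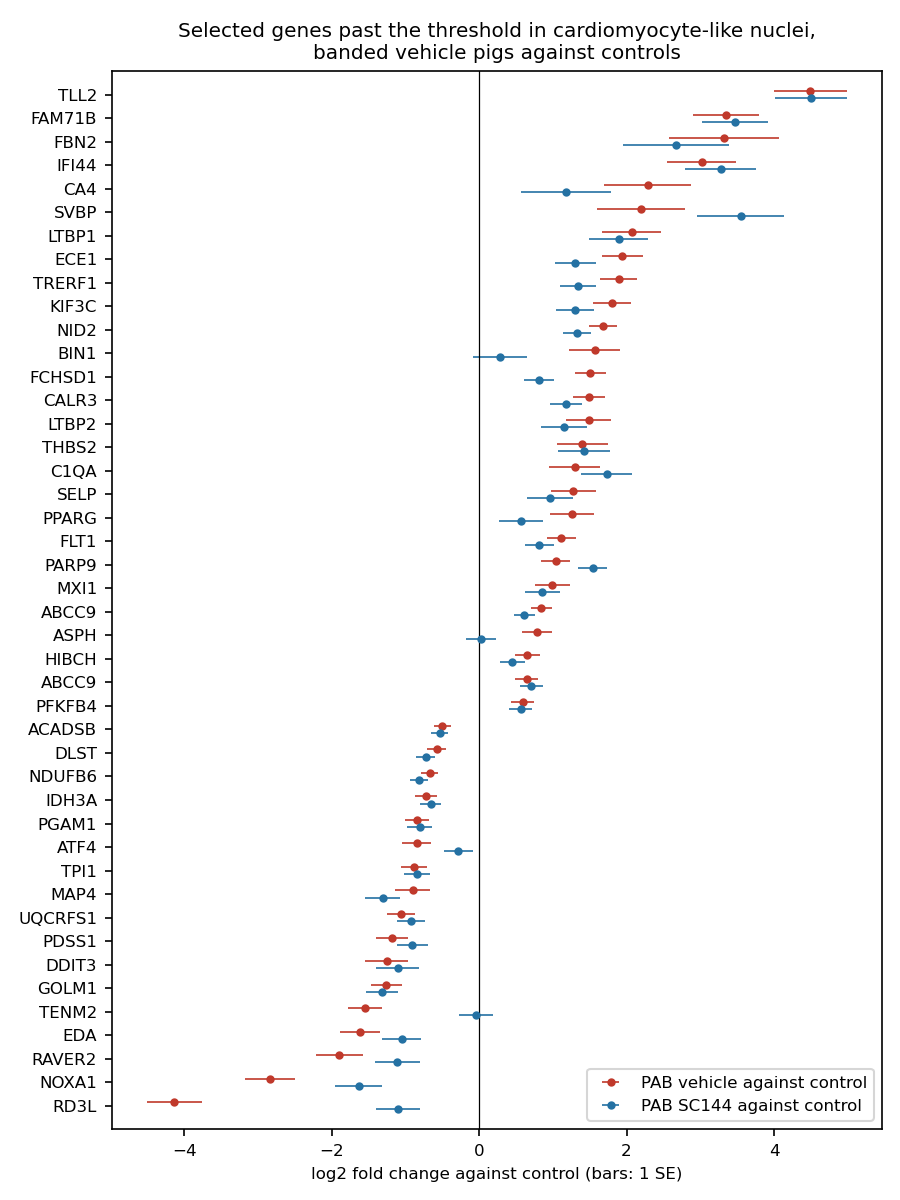
Log2 fold change ± SE of selected genes in cardiomyocyte-like nuclei, PAB-vehicle (red) and PAB-SC144 (blue) against control pigs. TLL2 rose by 4.49 and UQCRFS1 fell by 1.06 on the log2 scale between PAB-vehicle and control pigs.

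In fibroblast-like nuclei the genes of activated fibroblasts lay higher in PAB-vehicle than in control pigs, with 15 of 18 members above 0 and a median of 0.97 (camera adjusted p = 0.00111, adjusted p = 0.698 with an estimated correlation). Adjusted over the list alone, 2 members passed. FAP, a protease of the cell surface (0.92 ± 0.23, adjusted p = 0.166), and the matrix gene CILP (5.41 ± 1.5, adjusted p = 0.191) had the smallest p of the list and did not pass over all genes. MYO1D, an unconventional myosin, was the 1 gene of 11634 that rose (2.07 ± 0.25, adjusted p = 0.00980, edgeR quasi-likelihood, Benjamini-Hochberg). 1600 genes had an unadjusted p under 0.05 and DESeq2 called 202. edgeR called 0 without control pig 2 or 4 or vehicle pig 2, 9 and 5 without control pig 1 or 3, and 2 without vehicle pig 1. Interferon response genes lay lower (22 of 28 below 0, median -0.32, camera adjusted p = 0.00442, adjusted p = 0.698 with an estimated correlation), with 1 past the threshold adjusted over the list alone. The interferon call ended without control pig 2 or 3 (adjusted p = 0.0983 and 0.0520) and with doublets kept (adjusted p = 0.0521).

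Cardiomyocyte markers moved with these fibroblast groups, with a median of -1.0 in vehicle against control pigs (camera adjusted p = 0.00111, adjusted p = 0.698 with an estimated correlation), a call that ended without control pig 2 (adjusted p = 0.0983) and with doublets kept (adjusted p = 0.0521). Nuclei with at least 2% of their UMIs from cardiomyocyte markers were 3.57 ± 3.50% of fibroblast-like nuclei in control and 0.551 ± 0.273% in vehicle pigs, and 1.83% in control without control pig 2. Lists of cardiomyocyte biology lay lower by camera. Sarcomere genes had a median of -0.85 (adjusted p = 0.0176, adjusted p = 0.719 with an estimated correlation) and calcium handling genes of -0.66 (adjusted p = 0.00165, adjusted p = 0.698 with an estimated correlation). Cardiac ion channels had a median of -1.46 (adjusted p = 0.00111, adjusted p = 0.698 with an estimated correlation) and adrenergic signalling of -0.46 (adjusted p = 0.00467, adjusted p = 0.698 with an estimated correlation). The sarcomere call ended without control pig 2 or vehicle pig 1 or 3 (adjusted p = 0.287, 0.153 and 0.0552) and with doublets kept (adjusted p = 0.0850). The calcium and adrenergic calls ended without control pig 2 (adjusted p = 0.0983) for each. Without the nuclei rich in cardiomyocyte RNA, a setting added after the data were seen, these 4 lists gave camera adjusted p of 0.728, 0.501, 0.180 and 0.343. Activated fibroblast genes were still higher and interferon response genes still lower (adjusted p = 0.00446 for each).

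Vascular endothelial-like nuclei of PAB-vehicle pigs had higher interferon response genes (26 of 27 above 0, median 0.71) and higher endothelial activation genes (12 of 14, median 0.70) than those of controls. IFIT2, which binds viral RNA (1.85 ± 0.34, adjusted p = 0.0823), the guanylate-binding GTPase GBP2 (1.40 ± 0.28), and VWF of platelet adhesion (1.58 ± 0.41, adjusted p = 0.0927) had the smallest p of these lists and did not pass over all genes. Camera gave adjusted p = 9.47e-08 for interferon (adjusted p = 0.387 with an estimated correlation) and 0.00211 for activation (adjusted p = 0.387 with an estimated correlation). Adjusted over the list alone, 11 and 3 members were higher. TGF-beta signalling was higher (median 0.66, camera adjusted p = 0.00863, adjusted p = 0.387 with an estimated correlation), with LTBP1 at 0.99 ± 0.22. Endothelial fatty acid handling was higher (median 0.61, camera adjusted p = 0.00863, adjusted p = 0.399 with an estimated correlation), whose call ended with doublets kept (adjusted p = 0.104). Nuclear oxidative phosphorylation genes were lower (57 of 60 below 0, median -0.62, 19 past the threshold adjusted over the list alone, camera adjusted p = 4.86e-12, adjusted p = 0.387 with an estimated correlation). SDHD of complex II was at -1.13 ± 0.24 and COX5A of complex IV at -0.95 ± 0.21. A single gene passed over all 8249 by edgeR, ENSSSCG00000029076, which has no symbol (-2.95 ± 0.40, adjusted p = 0.0324) and was chosen after its values were seen. 2004 genes had an unadjusted p under 0.05, DESeq2 called 693, and edgeR fitted on the 2 groups alone called 1590. The count was 0 without control pig 2 or 3 or any one vehicle pig, and 4 and 2 without control pig 1 or 4. Without the nuclei rich in cardiomyocyte RNA edgeR called 1 gene, a higher one, and 0 genes shared with the fit of all nuclei.

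Cardiomyocyte markers were lower in the same endothelial nuclei (median -1.53, camera adjusted p = 3.08e-07, adjusted p = 0.399 with an estimated correlation) and endothelial markers higher (median 0.75, camera adjusted p = 2.46e-07, adjusted p = 0.387 with an estimated correlation). Nuclei rich in cardiomyocyte RNA were 34.9 ± 14.1% of vascular endothelial-like nuclei in control and 4.30 ± 2.18% in vehicle pigs. Without them, 3 of the 17 called lists were still called: TGF-beta signalling higher (adjusted p = 0.0224), and calcium handling and cardiomyocyte markers lower (adjusted p = 0.0183 for each). Interferon response genes then gave a camera adjusted p of 0.0537, endothelial activation 0.818 and oxidative phosphorylation 0.652. Fatty acid oxidation, the tricarboxylic acid cycle, glycolysis and branched-chain amino acid catabolism had medians of -0.83, -0.67, -0.73 and -0.92 with all nuclei, and adjusted p of 0.818, 0.677, 0.643 and 0.818 without the rich ones. The glycolysis call ended also without control pig 4 or vehicle pig 1 or 2 (adjusted p = 0.0594, 0.0607 and 0.0589) and with at least 1000 UMIs per nucleus (adjusted p = 0.0527).

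Pericyte-like nuclei had lower fatty acid oxidation genes (21 of 22 below 0, median -0.48, 6 past over the list alone) in PAB-vehicle than in control pigs, with the fatty acid transporter SLC27A1 at -1.46 ± 0.33, adjusted p = 0.190. Camera gave an adjusted p of 1.79e-05 (adjusted p = 0.489 with an estimated correlation). Oxidative phosphorylation had a median of -0.26 (camera adjusted p = 2.89e-05, adjusted p = 0.489 with an estimated correlation). Cardiomyocyte markers had a median of -1.66 (camera adjusted p = 1.40e-07, adjusted p = 0.489 with an estimated correlation). Pericyte markers had one of 0.39 (camera adjusted p = 3.80e-04, adjusted p = 0.525 with an estimated correlation). Nuclei rich in cardiomyocyte RNA were 14.5 ± 12.9% in control and 1.23 ± 0.488% in vehicle pigs, and 9.48% in control without control pig 2. Without those nuclei none of the 10 called lists passed by camera, with fatty acid oxidation at an adjusted p of 0.744. For single genes edgeR called 0, with 1230 at an unadjusted p under 0.05, and DESeq2 called 178. Without vehicle pig 2 edgeR called 1.

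Macrophage-like nuclei had higher mitochondrial genome transcripts in PAB-vehicle than in control pigs, with 11 of 11 members above 0, a median of 0.89 and 6 past the threshold over the list alone (camera adjusted p = 1.46e-04, adjusted p = 0.612 with an estimated correlation). These transcripts lie outside the nucleus and were few. Over nuclei of all classes their median share of UMIs was 0 to 0.0220% in control and 0.0164 to 0.0564% in vehicle pigs. COX2 (1.19 ± 0.32) and COX3 (1.02 ± 0.30) of complex IV had the smallest p. Ribosomal protein genes, a list for RNA quality, moved with them (median 0.24, camera adjusted p = 4.69e-05, adjusted p = 0.612 with an estimated correlation). NF-kB and inflammatory cytokine genes were lower (median -0.22, camera adjusted p = 0.0461, adjusted p = 0.612 with an estimated correlation), with the cytokine TNF at -1.48 ± 0.48 and NFKBIZ at -0.73 ± 0.22. The NF-kB call ended without control pig 2, 3 or 4 or vehicle pig 1, 2 or 4 (adjusted p = 0.122, 0.0873, 0.422, 0.127, 0.166 and 0.124) and with at least 1000 UMIs per nucleus (adjusted p = 0.208). Cardiomyocyte markers had a median of -1.63 (camera adjusted p = 1.23e-06, adjusted p = 0.612 with an estimated correlation), and nuclei rich in cardiomyocyte RNA were 5.72 ± 3.31% in control and 0.614 ± 0.326% in vehicle pigs. Without them the mitochondrial, ribosomal and NF-kB lists were still called (adjusted p = 0.00318, 0.00813 and 0.00813), and fatty acid oxidation (median -0.38, adjusted p = 8.22e-04, adjusted p = 0.605 with an estimated correlation) was not (adjusted p = 0.750). edgeR called 0 genes, with 1390 at an unadjusted p under 0.05, DESeq2 359, and edgeR 58 without control pig 1 and 1 without control pig 3 or vehicle pig 1.

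**Figure D3:**
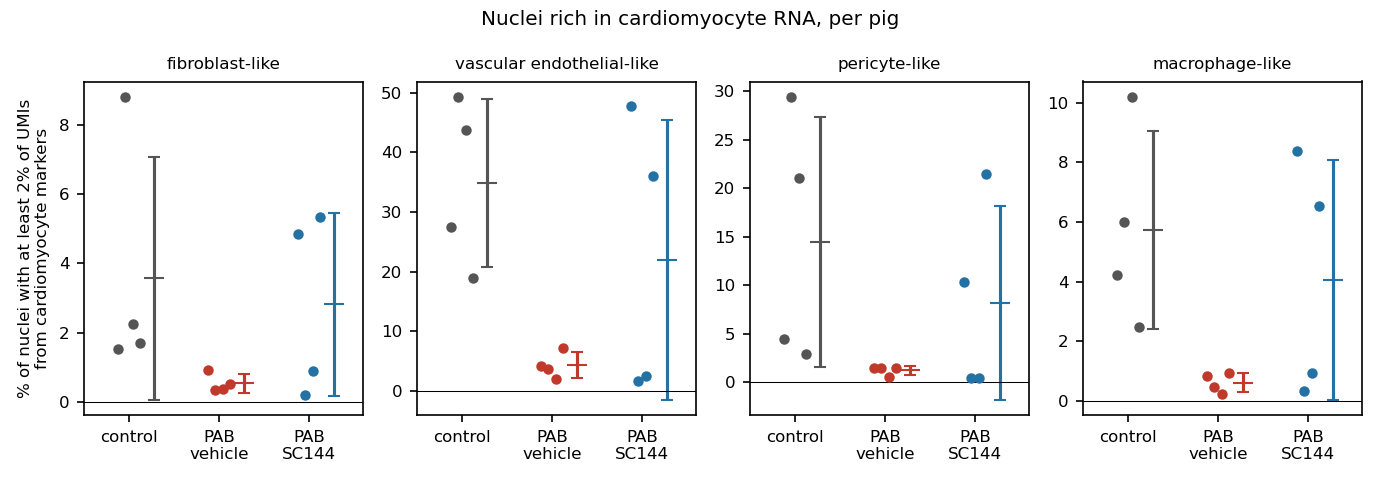
Percent of nuclei with at least 2% of UMIs from cardiomyocyte markers in 4 classes, one point per pig, with lines for the mean ± SD of 4 pigs. Vascular endothelial-like nuclei average 34.9% in control, 4.30% in PAB-vehicle and 22.0% in PAB-SC144 pigs.

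Interferon response genes lay higher in PAB-SC144 than in PAB-vehicle pigs in 4 of the 5 tested classes. In pericyte-like nuclei 20 of 21 members were above 0 (median 0.71, camera adjusted p = 6.39e-13, adjusted p = 0.0316 with an estimated correlation). There OAS1 (2.41 ± 0.39, adjusted p = 0.0396) and OAS2 (1.55 ± 0.25, adjusted p = 0.0396), sensors of double-stranded RNA, rose by edgeR over all genes. In fibroblast-like nuclei 25 of 28 were above 0 (median 0.62, camera adjusted p = 8.05e-11, adjusted p = 0.353 with an estimated correlation), with OAS2 at 1.37 ± 0.28 and OAS1 at 2.34 ± 0.48. Macrophage-like nuclei had 26 of 28 above 0 (median 0.42, camera adjusted p = 6.10e-09, adjusted p = 0.593 with an estimated correlation), with USP18, which removes ISG15 from proteins, at 0.47 ± 0.17. Cardiomyocyte-like nuclei had 21 of 27 above 0 (median 0.35, camera adjusted p = 0.00232, adjusted p = 0.498 with an estimated correlation), with the antiviral GTPase MX1 at 1.45 ± 0.44. By edgeR the members named in these 3 classes did not pass over all genes. The lowest edgeR adjusted p of any gene was 0.493 in fibroblast- and 0.589 in macrophage-like nuclei. In vascular endothelial-like nuclei the median was 0.054 (camera adjusted p = 0.996), and 0.27 (adjusted p = 8.21e-05) without the nuclei rich in cardiomyocyte RNA. Cardiomyocyte markers moved with the list in the 3 classes other than cardiomyocytes (medians 1.39, 0.96 and 1.31 in pericyte-, fibroblast- and macrophage-like nuclei). Ribosomal protein genes, a list for RNA quality or handling, moved with it in pericyte-, fibroblast- and cardiomyocyte-like nuclei (medians 0.23, 0.34 and 0.27, camera adjusted p = 2.61e-07, 8.05e-11 and 5.26e-07, and adjusted p = 0.607, 0.651 and 0.869 with an estimated correlation). Adjusted over the list alone, 8 members passed in pericyte-like and 6 in fibroblast-like nuclei. Without the rich nuclei camera gave adjusted p of 1.17e-16, 2.94e-11 and 1.34e-10 in pericyte-, fibroblast- and macrophage-like nuclei. By fry the interferon call did not hold in fibroblast-, macrophage- and cardiomyocyte-like nuclei, where 0 of 6, 8 and 8 called lists held. In each of the 4 classes the mean of the list was higher in 4 of 4 SC144 pigs than in every vehicle pig (exact p = 0.0286, adjusted p = 0.0635 over 20 tests chosen after the list results were seen).

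Few single genes changed under SC144. In cardiomyocyte-like nuclei RD3L rose (3.04 ± 0.39, adjusted p = 0.0347), the 1 gene of 14988 by edgeR quasi-likelihood, with 1538 at an unadjusted p under 0.05 and 135 by DESeq2. The edgeR count was 0 without SC144 pig 3, any one vehicle pig or control pig 2, 3 or 4, which enter the fit through the spread. It was 43 without SC144 pig 2 and 3 without SC144 pig 4. In pericyte-like nuclei PARP12, an interferon-induced mono-ADP-ribosyltransferase (1.5 ± 0.23, adjusted p = 0.0396), OAS1 and OAS2 rose, and FRRS1L, which helps assemble AMPA receptors, fell (-4.44 ± 0.61, adjusted p = 0.0396). These 4 genes came with 391 at an unadjusted p under 0.05 and 5 by DESeq2, and 1 gene passed without SC144 pig 1 and 0 without any other of the 8 pigs. edgeR called 0 genes in fibroblast-, vascular endothelial- and macrophage-like nuclei, with 629, 348 and 584 at an unadjusted p under 0.05 and 12, 1 and 7 by DESeq2. The genes tested in these were 11634, 8249 and 10343, and 8670 in pericyte-like nuclei. With no change a share of about 0.05 would have such a p, and the unadjusted counts in these 4 classes lie near it. A single gene passed without SC144 pig 2 in fibroblast-like nuclei and without vehicle pig 1 or SC144 pig 4 in macrophage-like nuclei.

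The genes of GP130 cytokines, receptors and signal carriers lay lower in cardiomyocyte-like nuclei of SC144 than of vehicle pigs (13 of 18 below 0, median -0.28, camera adjusted p = 0.0402, adjusted p = 0.869 with an estimated correlation). The receptor IL6R (ENSSSCG00000027628) was at -0.45 ± 0.16, adjusted p = 0.383, the kinase JAK2 at -0.38 ± 0.18 and IL6ST at -0.31 ± 0.18, adjusted p = 0.564. None of these passed over all genes. The call ended without vehicle pig 1 or 3 or SC144 pig 2, 3 or 4 (adjusted p = 0.0511, 0.231, 0.139, 0.189 and 0.0632) and with doublets kept (adjusted p = 0.0568). STAT3-responsive genes had a median of -0.060 over 24 members (camera adjusted p = 0.734). IL6ST was at 0.22 ± 0.18 in fibroblast-, 0.17 ± 0.22 in vascular endothelial-, -0.32 ± 0.18 in pericyte- and -0.19 ± 0.30 in macrophage-like nuclei, with adjusted p from 0.564 to 0.968 over the 5 classes. Banded vehicle against control pigs gave 0.031 ± 0.18, -0.067 ± 0.22, 0.20 ± 0.18 and -0.42 ± 0.30 in the same 4 classes. The sign of the IL6ST change turned in fibroblast-like nuclei after banding without control pig 1 (-0.10) or vehicle pig 3 (-0.057), and in vascular endothelial-like nuclei without control pig 2 (0.030) or vehicle pig 2 (0.0013) or 4 (0.013). Under SC144 it turned in vascular endothelial-like nuclei without SC144 pig 2 (-0.031) and in macrophage-like nuclei without vehicle pig 3 (0.034) or SC144 pig 2 (0.0097).

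Mitochondrial genome transcripts lay higher in cardiomyocyte-like nuclei of SC144 than of vehicle pigs (13 of 13 above 0, median 0.5, camera adjusted p = 2.10e-05, adjusted p = 0.869 with an estimated correlation), with COX1 of complex IV at 0.54 ± 0.19. In macrophage-like nuclei they lay lower (median -0.59, camera adjusted p = 0.0108, adjusted p = 0.596 with an estimated correlation), a call that ended without vehicle pig 4 or SC144 pig 2 (adjusted p = 0.980 and 0.25). These transcripts lie outside the nucleus and were few. Over nuclei of all classes their median share of UMIs was 0.0164 to 0.0564% in vehicle and 0.0300 to 0.0411% in SC144 pigs. Cell cycle genes were higher in cardiomyocyte-like nuclei (16 of 19 above 0, median 0.57, camera adjusted p = 0.00205, adjusted p = 0.869 with an estimated correlation), among them the replication helicase subunits MCM2 (1.71 ± 0.52) and MCM3 (2.09 ± 0.69). Sarcomere genes were higher as well (median 0.27, camera adjusted p = 0.0352, adjusted p = 0.869 with an estimated correlation), with the atrial myosin MYH6 at 2.48 ± 0.80 and the Z-disc gene TCAP at 0.92 ± 0.32. So were cardiomyocyte markers (median 0.27, camera adjusted p = 0.0347, adjusted p = 0.869 with an estimated correlation). The sarcomere and marker calls each ended without vehicle pig 3 or SC144 pig 3 (adjusted p = 0.262 and 0.403). Signs of handling moved with them: ribosomal protein genes had a median of 0.27 (camera adjusted p = 5.26e-07, adjusted p = 0.869 with an estimated correlation). Immediate early genes had one of 0.89 (camera adjusted p = 0.0442, adjusted p = 0.869 with an estimated correlation), with the stress factor ATF3 at 3.92 ± 1.05. By edgeR COX1, MCM2, MCM3, MYH6, TCAP and ATF3 did not pass over all genes. The immediate early call ended without vehicle pig 1 or 4 or SC144 pig 2 or 3 (adjusted p = 0.139, 0.171, 0.230 and 0.540). Cluster 8 held 59.0% of these nuclei in vehicle pigs and 23.9% in SC144 pigs, with 80.4% in SC144 pig 2 and 5.12% on average without that pig. Cluster 6 held 29.9% in SC144 pigs (10.7% without SC144 pig 3) and 4.76% in vehicle pigs, and cluster 3 21.7% (8.43% without SC144 pig 4) and 4.32% (2.36% without vehicle pig 1).

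In fibroblast-, vascular endothelial-, pericyte- and macrophage-like nuclei, cardiomyocyte markers lay higher in SC144 than in vehicle pigs, with medians of 0.96, 1.22, 1.39 and 1.31 (camera adjusted p = 1.69e-05, 1.17e-04, 8.19e-05 and 7.35e-07, and adjusted p = 0.651, 0.768, 0.640 and 0.593 with an estimated correlation). Nuclei rich in cardiomyocyte RNA were 2.82 ± 2.64%, 22.0 ± 23.5%, 8.20 ± 10.0% and 4.05 ± 4.02% in SC144 pigs, against 0.551%, 4.30%, 1.23% and 0.614% in vehicle pigs. The SC144 mean was 13.4% in vascular endothelial- and 2.61% in macrophage-like nuclei without SC144 pig 1, and 3.76% in pericyte-like nuclei without SC144 pig 4. The marker call ended without SC144 pig 1 (adjusted p = 0.0540) in fibroblast-, without SC144 pig 1 (adjusted p = 0.276) in vascular endothelial- and without SC144 pig 1 or 4 (adjusted p = 0.0887 and 0.141) in pericyte-like nuclei. In vascular endothelial-like nuclei oxidative phosphorylation genes were higher (median 0.22, camera adjusted p = 9.71e-04, adjusted p = 0.768 with an estimated correlation). Sarcomere genes were too (median 1.01, camera adjusted p = 1.17e-04, adjusted p = 0.768 with an estimated correlation), and 0 of 12 called lists passed by camera without the rich nuclei. The oxidative phosphorylation call ended also without vehicle pig 1 or SC144 pig 1 (adjusted p = 0.0680 and 0.796) and with doublets kept (adjusted p = 0.317), and the sarcomere call without SC144 pig 1 (adjusted p = 0.239). Pericyte-like nuclei had lower activated fibroblast genes (median -0.57, camera adjusted p = 0.0122, adjusted p = 0.607 with an estimated correlation; adjusted p = 0.274 without the rich nuclei), with the contractile actin ACTA2 at -0.80 ± 0.34. Fibroblast markers moved with them (median -0.27, camera adjusted p = 0.0103, adjusted p = 0.607 with an estimated correlation). The activated fibroblast call ended without vehicle pig 1 or 3 or SC144 pig 4 (adjusted p = 0.0784, 0.101 and 0.316) and with doublets kept (adjusted p = 0.0749), and that of the fibroblast markers without SC144 pig 4 (adjusted p = 0.316). Ribosomal protein genes were higher in fibroblast- (median 0.34, camera adjusted p = 8.05e-11, adjusted p = 0.651 with an estimated correlation) and pericyte-like nuclei (median 0.23, camera adjusted p = 2.61e-07, adjusted p = 0.607 with an estimated correlation). Without the rich nuclei these lists had adjusted p of 7.76e-11 and 3.52e-12. Resident macrophage genes were higher in macrophage-like nuclei (median 0.18, camera adjusted p = 0.0348, adjusted p = 0.593 with an estimated correlation; adjusted p = 0.00482 without the rich nuclei). The hyaluronan receptor LYVE1 was at 1.51 ± 0.52 and the growth factor IGF1 at 0.59 ± 0.26. By edgeR ACTA2, LYVE1 and IGF1 did not pass over all genes. The resident macrophage call ended without vehicle pig 2 or SC144 pig 2, 3 or 4 (adjusted p = 0.245, 0.0528, 0.149 and 0.0740) and with at least 1000 UMIs per nucleus (adjusted p = 0.0815).

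**Figure D4:**
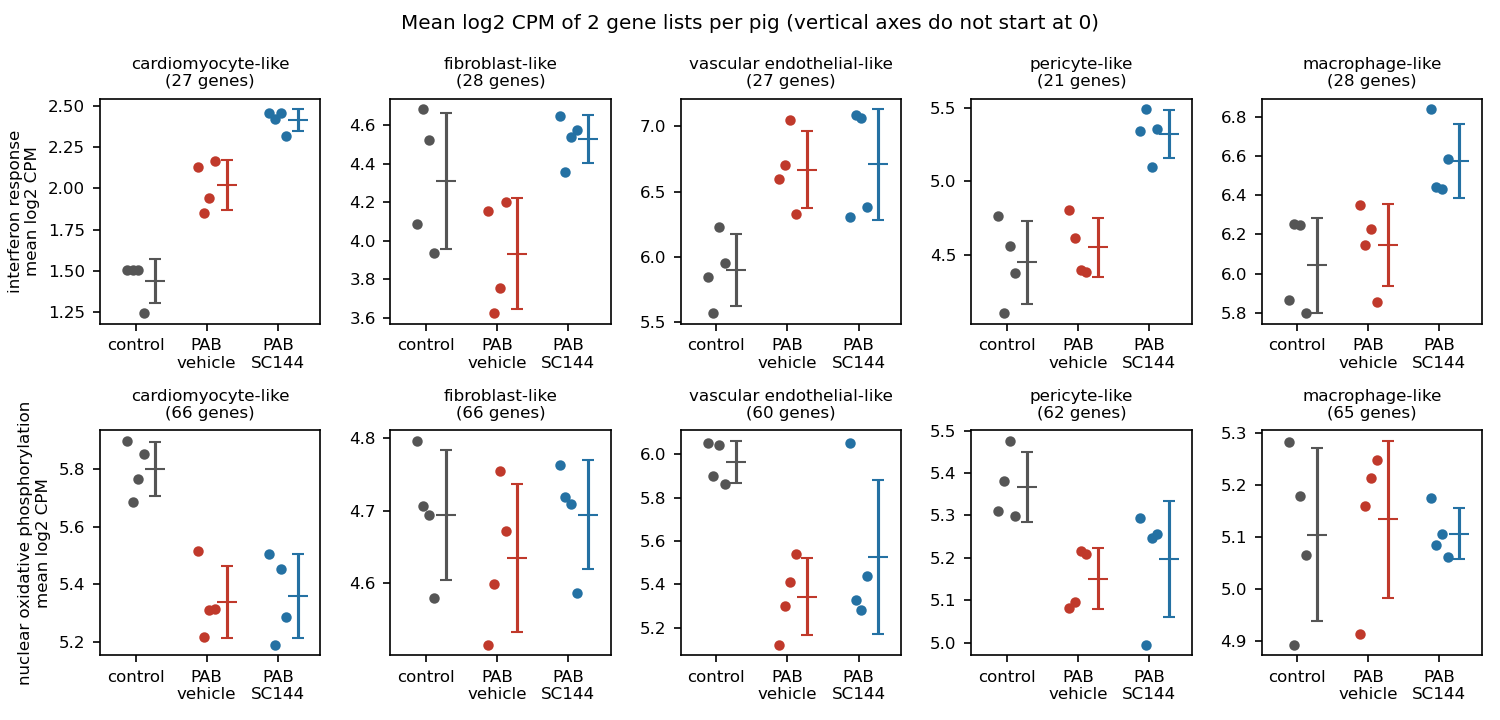
Mean log2 CPM of interferon response genes (top) and nuclear oxidative phosphorylation genes (bottom) in 5 classes, one point per pig, with lines for the mean ± SD of 4 pigs. For interferon response genes in pericyte-like nuclei the means are 4.45 in control, 4.55 in PAB-vehicle and 5.32 in PAB-SC144 pigs.

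The shares of sorted nuclei in SC144 pigs lay between the other two groups for several classes, and none differed from vehicle pigs after adjustment. Cardiomyocyte-like nuclei were 60.2 ± 11.9% in SC144 pigs, 11.1 percentage points above vehicle pigs (6.63 without SC144 pig 1), with 3 of 4 pigs above every vehicle pig (exact p = 0.171, adjusted p = 0.343). Macrophage-like nuclei were 9.62 ± 2.69% (2 of 4 below every vehicle pig, exact p = 0.0857, adjusted p = 0.236). T or NK cell-like nuclei were 4.97 ± 1.47% (3 of 4 below, exact p = 0.0571, adjusted p = 0.210). Neural or Schwann-like nuclei were 1.65 ± 0.521% against 2.32 ± 0.332% (3 of 4 below, exact p = 0.0857, adjusted p = 0.236). Pericyte-like (5.81 ± 3.32%), fibroblast-like (11.8 ± 4.19%) and vascular endothelial-like nuclei (4.52 ± 2.53%) had exact p of 0.486, 0.657 and 0.771. The fibroblast difference of -1.44 points was 0.628 without SC144 pig 1 and 3.25 among nuclei that are not cardiomyocyte-like, and the vascular endothelial difference of 0.444 was -0.00651 and -0.506 without SC144 pig 2 or 3. SC144 pigs gave 54115 kept nuclei after flow sorting and had 12.5% of barcodes left out as doublets.

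Against controls, PAB-SC144 pigs had 623 changed genes of 14988 in cardiomyocyte-like nuclei, 354 higher and 269 lower (edgeR quasi-likelihood, Benjamini-Hochberg). Genes that rose included TLL2 (4.50 ± 0.49, adjusted p = 0.00672), NID2 (1.32 ± 0.19) and FAM71B (3.47 ± 0.45, from a mean CPM of 0.594 in controls). So did PARP9 (1.54 ± 0.20, adjusted p = 0.00672), the interferon-induced ubiquitin ligase HERC6 (1.85 ± 0.26) and CLSPN, a mediator of the replication checkpoint (1.62 ± 0.21). The keratin KRT10 (2.29 ± 0.32) and the cholesterol carrier GRAMD1B (1.87 ± 0.28) rose as well. Among those that fell were RABGAP1L, a regulator of vesicle traffic (-1.16 ± 0.15, adjusted p = 0.00703), the calcium pump ATP2B1 (-1.46 ± 0.24), HMGCS1 of cholesterol synthesis (-1.01 ± 0.19) and the scaffold MAGI3 (-1.19 ± 0.22). GOLM1 (-1.32 ± 0.22), the mitochondrial membrane protein ARMCX3 (-1.13 ± 0.20) and RBM7 of nuclear RNA decay (-1.36 ± 0.25) also fell.

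Interferon response genes rose in 5 of 27 members and 21 adjusted over the list alone, with IFI44 at 3.28 ± 0.48 (median 0.90, camera adjusted p = 4.93e-12, adjusted p = 0.00632 with an estimated correlation). Nuclear oxidative phosphorylation genes fell in 22 of 66 members (41 adjusted over the list alone), with NDUFB6 at -0.81 ± 0.12 and ATP5L of ATP synthase at -0.81 ± 0.12. Their median was -0.47 (camera adjusted p = 9.26e-19, adjusted p = 0.433 with an estimated correlation). Mitochondrial genome transcripts were higher (13 of 13 above 0, median 0.68, camera adjusted p = 5.31e-05, adjusted p = 0.603 with an estimated correlation). COX1 rose by 0.86 ± 0.20. As given above, these transcripts lie outside the nucleus and were few. Of 19 tricarboxylic acid cycle genes 3 fell, DLST (-0.72 ± 0.13) and IDH3A (-0.66 ± 0.15) among them (camera adjusted p = 5.31e-05, adjusted p = 0.496 with an estimated correlation). SLC27A1 (-0.81 ± 0.17) and ETFA, which passes electrons on from fatty acid oxidation (-0.53 ± 0.12), fell (camera adjusted p = 0.337), as did PGAM1 (-0.80 ± 0.17) and TPI1 (-0.84 ± 0.18) of glycolysis (camera adjusted p = 0.535).

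Sarcomere genes were higher (median 0.31, camera adjusted p = 0.0340, adjusted p = 0.603 with an estimated correlation), with the myosin light chain MYL3 rising by 1.49 ± 0.36. Cardiomyocyte markers were higher too (median 0.31, camera adjusted p = 0.0389, adjusted p = 0.603 with an estimated correlation), with the creatine kinase CKM rising by 0.76 ± 0.19. Macrophage markers moved with them (3 of 21 rose, camera adjusted p = 0.0464, adjusted p = 0.662 with an estimated correlation), among them C1QA (1.73 ± 0.34) and C1QC (1.73 ± 0.39). The resident macrophage gene F13A1 rose by 0.96 ± 0.24 (list adjusted p = 0.0336, adjusted p = 0.548 with an estimated correlation). BGN (1.77 ± 0.42) and THBS2 (1.42 ± 0.35) of the matrix rose (camera adjusted p = 0.0340, adjusted p = 0.603 with an estimated correlation). So did FLT1 of endothelial activation (0.82 ± 0.20; camera adjusted p = 0.0148, adjusted p = 0.496 with an estimated correlation). The tropomyosin TPM2 (0.88 ± 0.19) and both ABCC9 IDs (0.71 ± 0.16 and 0.62 ± 0.15) rose too (mural list camera adjusted p = 0.0340, adjusted p = 0.496 with an estimated correlation). Of cell cycle genes ANLN of cytokinesis rose (1.13 ± 0.25) and CCNB2, a mitotic cyclin, fell (-0.86 ± 0.22), with a list median of 0.64 (camera adjusted p = 0.0389, adjusted p = 0.603 with an estimated correlation). SVBP rose (3.55 ± 0.59) and MAP4 fell (-1.30 ± 0.24), and the stress sensor SESN2 rose (1.37 ± 0.30) and DDIT3 fell (-1.11 ± 0.29). Mean CPM in controls was low for SVBP (0.164), SESN2 (0.249), BGN (0.471), C1QA (0.853) and C1QC (0.557). IL6ST was at 0.073 ± 0.18, adjusted p = 0.845, and at -0.021 or -0.019 without control pig 1 or SC144 pig 2. The endothelial activation call ended without SC144 pig 3 (adjusted p = 0.0917). The resident macrophage call ended without control pig 4 or SC144 pig 3 (adjusted p = 0.0609 and 0.122) and the mural call without control pig 4 or SC144 pig 3 (adjusted p = 0.0641 and 0.120). Matrix genes lost their call without control pig 1 or 4 or SC144 pig 3 (adjusted p = 0.0828, 0.0712 and 0.355). Cell cycle genes lost theirs without control pig 2 or 4 or SC144 pig 1 or 3 (adjusted p = 0.0554, 0.0505, 0.194 and 0.122) and sarcomere genes without control pig 3 or 4 or SC144 pig 1 or 3 (adjusted p = 0.131, 0.0505, 0.0729 and 0.186). For cardiomyocyte markers the call ended without control pig 3 or 4 or SC144 pig 1 or 3 (adjusted p = 0.139, 0.0609, 0.0729 and 0.252). For macrophage markers it ended without control pig 2, 3 or 4 or SC144 pig 1 or 3 (adjusted p = 0.143, 0.0799, 0.0614, 0.0729 and 0.408) and with at least 1000 UMIs per nucleus (adjusted p = 0.0508).

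DESeq2 called 1602 genes in this comparison, and 3476 had an unadjusted p under 0.05 by edgeR. The edgeR count was 203 and 17 without control pig 2 or 4, 230, 289 and 344 without SC144 pig 2, 3 or 4. It was 137 in a fit of the 2 groups alone and 225 in thinned libraries.

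A single gene, RD3L, changed with banding (-4.13 ± 0.38) and changed the opposite way under SC144 (3.04 ± 0.39) in cardiomyocyte-like nuclei, with mean CPM of 1.22, 0.0627 and 0.565 in control, vehicle and SC144 pigs. The 544 genes higher after banding had median changes of 1.23 with banding, -0.31 under SC144 and 0.87 between SC144 and control pigs, and the 318 lower genes -0.77, 0.15 and -0.60. These genes were chosen on the same vehicle and control pigs, which by itself moves the latter 2 values. Both comparisons share the vehicle pigs, and in 20 simulations with no true change the count was 0 and the covariance of the 2 changes -0.0505 on average, against -0.114 in the data (difference -0.0632). With no banding effect simulated, few genes could pass, so that count of 0 was close to fixed beforehand. The correlation was -0.451, and -0.483 in the simulations. Independent lists of these sizes would share 0.0212 genes changed opposite ways. With the vehicle pigs split 2 and 2 between the comparisons, the count was 0 in all 6 splits by edgeR and the covariance -0.0478 to -0.0832. The simulated covariance comes from shared vehicle pigs and is no chance level for these splits, which share none. There 60 of 87, 32 of 43, 8 of 14, 388 of 582, 149 of 227 and 60 of 75 genes past the threshold after banding had the opposite sign under SC144. DESeq2 counted 52 opposite genes, and edgeR 25 without SC144 pig 2 and 0 without control pig 2, 3 or 4, SC144 pig 3 or any one vehicle pig. For the counts of 52 and 25, independent lists of those sizes would share 7.86 and 1.44 genes, without allowing for the shared vehicle pigs.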

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

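Among the tests here, that of cardiomyocyte RNA for both the endothelial oxidative phosphorylation and the interferon pattern, that of cytoplasmic RNA for the cardiomyocyte pattern, and the 5 tests of differences between classes were chosen after the results were seen. The spread used to read the cytoplasmic RNA test was also added after its value was seen.

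Camera called interferon response genes in opposite directions with banding in different classes. The change of the list's mean was 0.957 higher on the log2 scale in cardiomyocyte- than in fibroblast-like nuclei, and in fibroblast- against vascular endothelial-like nuclei the difference was -1.14. In fibroblast-like nuclei alone the list's mean changed by -0.374, with 2 of 4 vehicle pigs below every control pig (exact permutation p = 0.171, adjusted p = 0.343). Ribosomal protein genes differed by -0.426 between cardiomyocyte- and macrophage-like nuclei with banding. Mitochondrial genome transcripts under SC144 differed by 0.912 between cardiomyocyte- and macrophage-like nuclei and by 0.724 between fibroblast- and macrophage-like nuclei. Each of the 5 differences was put to a test over pigs (exact permutation p = 0.0286, the smallest that can be had, and the same after adjustment over 5). The 5 were chosen because camera had called the list in opposite directions, so these p are not independent evidence of a difference. Of the calls behind them, the endothelial interferon call ended without the nuclei rich in cardiomyocyte RNA (adjusted p = 0.0537) and the fibroblast one without control pig 2 or 3 (adjusted p = 0.0983 and 0.0520) and with doublets kept (adjusted p = 0.0521). The ribosomal call in cardiomyocyte-like nuclei ended without control pig 1 or 2 or vehicle pig 1 or 2 (adjusted p = 0.485, 0.0982, 0.129 and 0.455). The mitochondrial call in fibroblast-like nuclei (median 0.24, camera adjusted p = 0.00479, adjusted p = 0.651 with an estimated correlation) ended without vehicle pig 1 or 2 or SC144 pig 3 (adjusted p = 0.212, 0.187 and 0.108), and that in macrophage-like nuclei without vehicle pig 4 or SC144 pig 2 (adjusted p = 0.980 and 0.25).

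A single pig lay far from the other 3 of its group in 14 of 297 groups searched, and chance alone picks out about 1 in 20. In cardiomyocyte-like nuclei these were, in CPM, ARMCX3 at 22.1 and KIF3C at 22.4 in vehicle pig 1, UQCRFS1 at 31.6 in vehicle pig 2, NID2 at 952 and DDIT3 at 15.7 in vehicle pig 3, HIBCH at 26.2 in control pig 3 and C1QA at 0.633 in control pig 4. In SC144 pigs they were RAVER2 at 2.55 in pig 2, MYL3 at 138 and ATF4 at 51.1 in pig 3, and BIN1 at 0.676 in pig 4. FRRS1L lay at 1.57 CPM in pericyte-like nuclei of control pig 1. Nuclei rich in cardiomyocyte RNA were 8.81% of fibroblast-like nuclei in control pig 2 and 0.503% of pericyte-like nuclei in vehicle pig 3.

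Nuclear oxidative phosphorylation genes were lower in vascular endothelial-like nuclei of PAB-vehicle than of control pigs (median log2 change -0.62). In libraries thinned to one depth the median was -0.657. Random thinning keeps each gene's expected share of the counts, so it could hardly move the median and does not test summed depth. Without the nuclei rich in cardiomyocyte RNA the median was -0.00797 and the list was no longer called, which is consistent with cardiomyocyte RNA in the endothelial nuclei of control pigs. Whether that RNA is free RNA, doublets below the score threshold or transcripts of the endothelial nuclei themselves stays open, as does an effect of banding on endothelial metabolism, which is an untested hypothesis.

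Interferon response genes were higher under SC144 in fibroblast-, pericyte- and macrophage-like nuclei. Cardiomyocyte RNA as the whole source is argued against by the level of the list in cardiomyocyte-like nuclei. Its mean log2 CPM over the members tested was 2.41 there in SC144 pigs. In vehicle pigs it was 3.93 in fibroblast-, 4.55 in pericyte- and 6.15 in macrophage-like nuclei, so cardiomyocyte RNA would lower it. Leaving out the rich nuclei could therefore hardly end the call and does not test this source (highest camera adjusted p = 1.34e-10 over the 3 classes). A single pig is argued against by the list's mean, which in each class was higher in 4 of 4 SC144 pigs than in every vehicle pig. Exact permutation gave p = 0.0286 (adjusted p = 0.0635) in each. With each of the 8 pigs left out in turn, camera at its preset correlation gave a highest adjusted p of 4.78e-05. That p allows for little correlation between the genes, and with an estimated correlation only the pericyte call held. By fry the fibroblast and macrophage calls did not hold. In thinned libraries the medians were at least 0.839 times as large. Random thinning keeps each gene's expected share of the counts, so these medians do not test depth. An effect of SC144 may remain as a hypothesis found and tested on the same data. An infection or a handling difference shared by the 4 SC144 pigs stays open, because the labels give no batch and ribosomal protein genes, a list for RNA quality or handling, moved with the list in fibroblast- and pericyte-like nuclei (medians 0.34 and 0.23, 0.057 in macrophage-like nuclei).

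Nuclear oxidative phosphorylation genes were lower in cardiomyocyte-like nuclei of PAB-vehicle than of control pigs (median -0.44). A single pig is argued against by the list's mean, which was lower in 4 of 4 vehicle pigs than in every control pig. Exact permutation gave p = 0.0286 (adjusted p = 0.0635). With each of the 8 pigs left out in turn, camera at its preset correlation gave a highest adjusted p of 1.16e-13. That p allows for little correlation between the genes, and with an estimated correlation the list was not called. In thinned libraries the median was -0.436. Random thinning keeps each gene's expected share of the counts, so this median does not test summed depth. Less cytoplasmic RNA in the nuclei of banded pigs and lower transcription cannot be told apart: the 13 mitochondrial genome transcripts, which lie outside the nucleus, had a median of 0.149, but the gap between them and the nuclear list overlapped between groups. That gap was 0.625 log2 higher in vehicle pigs, with 3 of 4 above every control pig (exact permutation p = 0.0571). The reading written first took a median of 0 or more as against less cytoplasmic RNA. The gap was added after 0.149, which met that reading, was seen. An effect of banding on cardiomyocyte metabolism stays open as an untested hypothesis.

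The same 8 pigs can be split into 4 and 4 in 35 ways, the real one included, and the number of splits with as many genes is given with the highest count of the others. In cardiomyocyte-like nuclei no other split called nearly as many genes for PAB-vehicle against control (862 genes, 1 of 35, highest other 1). The same held for SC144 against control (623 genes, 1 of 35, highest other 5). This argues against chance but does not exclude it, since the smallest possible outcome is 1 of 35. Mixed splits also hold the group difference as spread within their groups, which lowers their counts. Without control pig 4 the counts were 115 and 17. The splits do not settle whether chance gave the 1 gene in vascular endothelial-like nuclei after banding (1 of 35, highest other 0) and the 4 genes in pericyte-like nuclei under SC144 (1 of 35, highest other 0). These 2 are small counts over 11 such tests, and 6 and 7 of the 8 fits with a pig left out called 0 genes there. Without the nuclei rich in cardiomyocyte RNA the endothelial fit shared 0 genes with that of all nuclei. Chance cannot be excluded for the 1 gene in fibroblast-like nuclei after banding (4 of 35, highest other 7) and the 1 gene in cardiomyocyte-like nuclei under SC144 (7 of 35, highest other 209). The counts of 0 by edgeR were reached in every split. After banding this was in pericyte- (35 of 35, highest other 1) and macrophage-like nuclei (35 of 35, highest other 2), with 1230 and 1390 genes at an unadjusted p under 0.05 and 178 and 359 by DESeq2. Under SC144 it was in fibroblast- (35 of 35, highest other 5), vascular endothelial- (35 of 35, highest other 486) and macrophage-like nuclei (35 of 35, highest other 1), with 629, 348 and 584 genes at an unadjusted p under 0.05 and 12, 1 and 7 by DESeq2. These unadjusted counts, of 11634, 8249 and 10343 genes tested, lie near the share of 0.05 that no change would give. Splits of SC144 and vehicle pigs that called 209 genes in cardiomyocyte- and 486 in vascular endothelial-like nuclei, far above the real counts, point to a structure of the samples that the groups do not follow.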

How the results depend on the processing

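The settings without nuclei rich in cardiomyocyte RNA and with clusters rich in doublets kept were chosen after the data were seen. With pigs left out set aside, 144 of 202 values of main results, 440 of 741 of called lists and 870 of 978 of named genes kept their direction and side of the threshold (counts within 1.5 times). RLE factors changed 0 of them by edgeR or camera. Over all settings the median log2 change of all genes moved by at most 0.0903. In simulations with the spread and depth of these pigs, of log2 changes of 1, 14 to 44% were recovered, and of 2, 77 to 93%. The cause was not tested for the changes below, except that thinning removes counts.

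DESeq2 called 1785, 135 and 1602 genes in cardiomyocyte-like nuclei for banding, SC144 against vehicle and SC144 against control, 202 and 12 in fibroblast-, 693 and 1 in vascular endothelial- and 359 and 7 in macrophage-like nuclei for banding and SC144, 178 in pericyte-like nuclei for banding, and 52 genes changed opposite ways. A fit of the 2 groups alone gave 0 and 137 in cardiomyocytes for SC144 against vehicle and control, 36, 1590, 205 and 305 in fibroblasts, endothelium, pericytes and macrophages for banding, and 2 in pericytes for SC144. Thinned libraries gave 385, 0 and 225 in cardiomyocytes, 0 in endothelium for banding and 1 in pericytes for SC144. No low-count filter gave 64, 16 and 10 in endothelium, pericytes and macrophages for banding. At least 1000 UMIs gave 3 in endothelium for banding and 1 in pericytes for SC144. Doublets kept gave 0, 1 and 2 in cardiomyocytes, endothelium and pericytes for SC144 and 2 in fibroblasts for banding, and clusters rich in doublets kept gave 0 there. Leiden resolution 0.5 gave 0 and 6 in endothelium and pericytes for banding and 1 in pericytes for SC144. Leaving out genes higher in cardiomyocytes gave 4 and 1 in endothelium and macrophages for banding. The 6 splits of the vehicle pigs gave 0 genes changed opposite ways each.

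The replicate numbers were not taken as pairs, since not every pair of pigs of the same number was correlated above 0.1: 3 of 12 were (-0.189 to 0.199). All of these lay among the 4 vehicle and SC144 pairs (0.193, 0.150, -0.0568 and 0.199), and 5 of 12 pigs lay closest to their own number. With the number as a block edgeR gave 2 and 300 genes in cardiomyocytes for SC144 against vehicle and control, 0 and 0 in fibroblasts and endothelium for banding, 1 and 0 in endothelium and pericytes for SC144, and 2 changed opposite ways. Of 110 list calls 106 held. GP130 and immediate early genes in cardiomyocytes for SC144 (adjusted p = 0.0708 for each), and mitochondrial biogenesis and NF-kB genes in macrophages for banding (adjusted p = 0.0680 and 0.0735), did not pass.

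With a pig of the compared groups left out, counts ranged from 115 to 1004, 0 to 43 and 17 to 742 in cardiomyocytes for the 3 comparisons. Without SC144 pig 2, which enters the banding fit through the spread, 1150 genes passed for banding in cardiomyocytes. For banding and SC144 the counts ranged from 0 to 9 and 0 to 1 in fibroblasts, 0 to 1 and 0 to 1 in pericytes, 0 to 58 and 0 to 1 in macrophages, and 0 to 4 in endothelium for banding, and from 0 to 25 for genes changed opposite ways. The fibroblast share ranged from -1.85 to 3.56 percentage points for banding and -2.39 to 0.628 for SC144, and the endothelial share from -0.506 to 1.30 for SC144. The fibroblast share for banding was -0.822 with doublets kept, -0.538 with clusters rich in doublets and -14.4 among nuclei that are not cardiomyocytes, and that for SC144 3.25 among the latter.

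Of 110 called lists, 2 were still called with an estimated correlation and 11 by fry. Without nuclei rich in cardiomyocyte RNA 18 of the 81 called outside cardiomyocytes were. With lists not called before included, the number of calls was 12 by fry and 53 without the rich nuclei, where cardiomyocytes stayed as they were. Without those nuclei the direction turned for 12 lists, none called: after banding sarcomere in fibroblasts, pericytes and macrophages (adjusted p = 0.728, 0.983 and 0.649), oxidative phosphorylation in endothelium and pericytes (0.652 and 0.675), the tricarboxylic acid cycle and glycolysis in endothelium (0.677 and 0.643), cardiac stress genes in endothelium and pericytes (0.711 and 0.479) and cardiomyocyte markers in macrophages (0.991). Under SC144 they were endothelial markers in endothelium (0.827) and fatty acid oxidation in pericytes (0.944).

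The IL6ST change, which passed in no class, turned sign in fibroblasts for banding at -0.0086 in thinned libraries and -0.033 without nuclei rich in cardiomyocyte RNA. In endothelium it was 0.091 with doublets kept and 0.091 without the rich nuclei for banding, and -0.0016 with doublets kept and -0.022 at Leiden resolution 0.5 for SC144. In macrophages for SC144 it was 0.075 in thinned libraries. With a pig left out it ranged from -0.10 to 0.10 in fibroblasts, -0.23 to 0.030 and -0.031 to 0.34 in endothelium for banding and SC144, -0.34 to 0.034 in macrophages for SC144 and -0.021 to 0.22 in cardiomyocytes for SC144 against control.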

Other observations

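The values of cardiomyocyte clusters and of cluster 10, the 8 tests of unnamed clusters and the spread used to read the receptor test were chosen after the data were seen. A small cardiomyocyte-like cluster (cluster 23) had as its leading genes the antiviral sensors DDX60 and DDX58, the ubiquitin-like modifier ISG15, PARP9 and USP18. It held 0.110% of cardiomyocyte-like nuclei in control, 0.154% in PAB-vehicle and 0.525% in PAB-SC144 pigs, and 0.338% without SC144 pig 1, which supplied 40.9% of its nuclei. Cluster 6, led by the stress genes RRAD, NR4A3, NPPB, ANKRD1 and XIRP1, held 8.26%, 4.76% and 29.9%, and SC144 pig 3 alone supplied 51.2% of its nuclei (10.7% without that pig, and 4.22% in controls without control pig 1). Cluster 3, led by MYH6 of atrial myosin, ACTC1 and FHL2, held 4.69%, 4.32% and 21.7%, with 36.3% of its nuclei from SC144 pig 4 (8.43% without it, 3.03% in controls without control pig 3 and 2.36% in vehicle pigs without vehicle pig 1).

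A cycling cluster (cluster 10) with DIAPH3, CENPF and TOP2A of mitosis as leading genes, and with 8 of 22 fibroblast markers higher, held 1.31% of nuclei in control, 0.507% in PAB-vehicle and 2.27% in PAB-SC144 pigs. Exact permutation gave p = 0.0857 after banding (adjusted p = 0.229, -0.804 percentage points) and p = 0.143 under SC144 (adjusted p = 0.286, 1.76 percentage points) over 8 tests, 4 pigs per group. SC144 pig 1 supplied 32.6% of its nuclei. The mean was 1.53% in SC144 pigs without that pig and 0.976% in controls without control pig 2, which makes both differences over 1.5 times smaller. The shares come from flow-sorted nuclei.

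CYP1A1, a detoxifying enzyme that the aryl hydrocarbon receptor switches on, was at 3.12 ± 0.55 in vascular endothelial-like nuclei of SC144 against vehicle pigs (edgeR adjusted p = 0.624, DESeq2 adjusted p = 5.77e-04), and TIPARP, another target, at 0.94 (edgeR adjusted p = 0.861). CYP1A1 was chosen after its values were seen. A hypothesis was that SC144 may activate that receptor. The 4 other targets tested, NQO1, NFE2L2, XDH and TXNRD1, had a median of -0.156 with an SD of 0.424 over genes, 1 of them above 0 (limma camera, unadjusted p = 0.624). In other classes 4 of 4 in fibroblast-, 4 of 4 in macrophage-, 2 of 3 in pericyte- and 3 of 8 in cardiomyocyte-like nuclei were above 0 (medians 0.219, 0.358, 0.0662 and -0.190, limma camera, unadjusted p = 0.196, 0.0451, 0.877 and 0.289). For macrophage-like nuclei limma camera gave an unadjusted p of 0.127 with an estimated correlation. TIPARP, which is not in these counts, was at -0.210 in fibroblast-, -0.037 in macrophage-, -0.019 in cardiomyocyte- and 0.534 in pericyte-like nuclei. The reading set beforehand took a median of 0 or below in the endothelial nuclei as against activation, and -0.156 met it. Read with the SD over genes, added afterwards, activation and its absence cannot be told apart there with 4 genes that go both ways.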
